A study of Homo sapiens with 2 samples.

How the data were processed

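KMS34 cells, an established human multiple myeloma line, were cultured for 24 hours with RK-552 at 5 μM or with 0.1% dimethylsulfoxide (DMSO), the solvent used as vehicle control, and total RNA was hybridised to an Agilent expression microarray. Per the labels, RNA from the DMSO culture was labelled with Cy3 and RNA from the RK-552 culture with Cy5. There was 1 sample per group, no dye-exchanged array and no second culture, so the dye and the treatment cannot be told apart and no spread between cultures could be measured.

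The deposited table gave 1 linear intensity per spot and sample, with 62973 spots of which 2072 were controls. Agilent Feature Extraction 12.0.3.1 was named in the submitters' processing notes. The background subtraction and dye normalization behind the deposited intensities were not given in the sources used here. The 75th percentiles of the probe intensities were 94.6 with DMSO and 93.9 with RK-552, so the columns had nearly the same scale as deposited. At the low end, 20652 spots (33.9% of the spots that were not controls) had an intensity below 4.5 with DMSO and below 1.8 with RK-552. Their log2 difference was −1.31 ± 0.05 (median ± SD across spots), nearly a constant, and the 308 negative-control spots had medians of 3.88 and 1.57 in the same columns. Values in this range therefore carried the array's lower limit in each column rather than a measured level, and a fold taken there has no meaning.

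Spots were matched to samples by the column names. Across the repeat spots of probes with a level of 64 or more, deviations from the probe mean in the DMSO column correlated with those in the RK-552 column (Pearson r = 0.55, Spearman rho = 0.64, across 2580 spots that are not independent replicates). Such a relation arises when both columns come from the same physical spots, so the 2 samples were treated as the channels of 1 two-colour array.

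The 60901 spots that were not controls held 58201 probes. Of these probes, 57901 were spotted once and 300 were spotted 10 times. Log2 values were averaged over the spots of a probe, and the log2 difference was RK-552 minus DMSO. A probe entered the comparison if it lay above a floor in both samples. No detection flag was used here, and the floor was the 50th percentile of the probes in each column, an intensity of 5.12 with DMSO and 5.17 with RK-552. The level of a probe is the geometric mean of its 2 intensities. Saturation could not be assessed from the intensities alone, and the number of arrays limits the precision.

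The probes were identified by the manufacturer's probe ID only. None of the 58201 IDs matched an identifier in the reference gene table of the human assembly, so no probe was assigned to a gene, a transcript or a genomic position. For this reason 35 gene lists fixed before the data were examined, including plasma cell identity, cell cycle, stress response and marker lists of other cell types, could not be evaluated, and 0 were. The transcript of the compound's stated target, MMSET (NSD2), was not analysed here for the same reason. Counts planned per gene were made per probe, the planned spread between probes of one gene was replaced by the spread between spots of one probe, and the setting with the brightest probe per gene was not run. The rule for naming single features, also fixed before the data were examined, took the 12 with the largest and the 12 with the smallest log2 difference above the floor. Without gene names only the first 2 IDs in each direction are printed.

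No p-value was computed for the treatment, because 1 sample per group gives none. Differences were described by size, with 2-fold as the threshold, and set against the SD between repeat spots, which covers hybridisation and scanning noise on the array but not labelling, dye or culture. Counting was tested on simulated data for this comparison. Log2 differences for the 26930 probes above the floor were drawn with the median SD between spots at each level, and 200 probes were changed by known folds. All 50 probes changed 4-fold and all 48 changed 8-fold were called, as were 39 of 44 changed 2.5-fold (88.6%) and 5 of 58 changed 1.5-fold (8.62%). Of 26730 unchanged simulated probes 592 passed 2-fold, and 0 of these were among the 16012 with a level of 64 or more. The simulated noise was normal and held no stray spots. At a level of 64 or more its SD was far below 2-fold, so the 0 followed from the setting. It is not a rate of false calls for bright probes. No floor was applied to the simulated values. In the data a change can carry a dim probe below the floor in 1 sample, and these shares do not account for that.

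Alternatives were centring on the median of all probes, an equal 75th percentile, quantile normalization, loess of the log2 difference on the level (span 0.2), 50 added to both intensities, floors at the 70th percentile, in at least 1 sample or none, and thresholds of 1.5-fold and 3-fold. Floors at the highest negative-control spot (8.97 with DMSO and 3.86 with RK-552) and at a level of 64 were chosen after seeing the data. Intervals of shares and counts are exact 95% binomial or Poisson intervals and cover counting error only. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.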

Results

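Gene expression was profiled in KMS34 cells after 24 hours with RK-552, described by the submitters as an inhibitor of MMSET, or with the DMSO vehicle. MMSET, also named NSD2, is a histone methyltransferase. The comparison asked which transcripts differed in abundance between the cultures with and without the inhibitor. There was 1 sample per group, so every difference below lacks a replicate check, and SDs are between spots or probes of the array. Of 58201 probes, 26930 (46.3%) lay above the floor in both samples. Their median intensity was 123 with DMSO and 124 with RK-552. Because the floor was the 50th percentile of each column, the share above it could not exceed 50% and is not a detection rate.

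As deposited, intensities with RK-552 lay within 2-fold of those with vehicle for nearly all probes above the floor. Of the 26930 probes above the floor, 355 were at least 2-fold higher and 176 at least 2-fold lower with RK-552, together 1.97%. The median log2 difference was 0.01, and the quartiles were −0.13 and 0.16. Across probes, which are not independent replicates, the log2 intensities of both samples correlated with r = 0.994 (Spearman rho = 0.992). A median near 0 can come from dye normalization, and r depends on the range of intensities. Neither value excludes a shift common to all probes. The share of higher probes among the 2-fold differences was 66.9% as deposited. It was 95% (1046 higher and 55 lower) after centring on the median of all probes, which lay at −0.31 because of the values at the lower limit, and 51.2% (256 higher and 244 lower) after quantile normalization. Other floors and offsets turned it, to 37.0% (1052 and 1788) for probes above the floor in at least 1 sample, 26.4% (106 and 296) above the highest negative-control spot of each column, 20% (1 and 4) at a level of 64 or more and 10% (1 and 9) with 50 added to both intensities. Some of these outcomes follow from the setting itself. The floor in at least 1 sample admits values at the lower limit. The negative-control floor drops higher and admits lower values, and quantile normalization can draw the share towards 50%. At a level of 16 to 64, where all probes lay above both floors, 66 were higher and 39 lower. No balance between higher and lower probes over all levels can be given. Relative to the main scaling, centring moved the median of the probes above the floor to 0.32.

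The 2-fold differences lay among dim probes. Probes with a level under 64 gave 99.1% of them, 354 higher and 172 lower out of 10801. Among the 16129 probes with a level of 64 or more, 1 was at least 2-fold higher and 4 at least 2-fold lower. Among the 10432 probes with a level of 256 or more, 0 were 2-fold higher and 1 was 2-fold lower, and 99.8% lay within 1.5-fold. The central 95% of these brighter probes spanned log2 differences from −0.25 to 0.32. At the threshold of 1.5-fold, 16 of them were higher and 1 was lower.

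**Figure D1:**
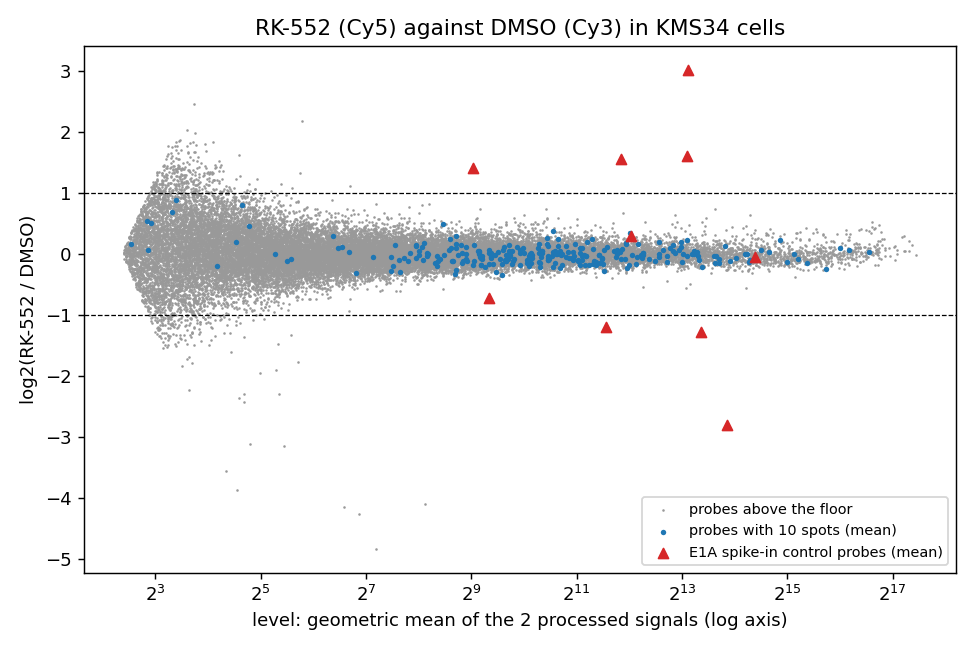
Each grey point is a probe above the floor, with its level (geometric mean of the DMSO and RK-552 intensities, log axis) on the x axis and log2(RK-552 / DMSO) on the y axis; blue points are means of probes with 10 spots, red triangles are means of E1A spike-in control probes, and dashed lines mark 2-fold. Nearly all 2-fold differences lie below a level of 64, while the controls, with median intensities of 321 or more, reach from −2.79 to 3.02.

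The array could register large ratios between the dyes for bright control probes. The 10 E1A probes, controls for RNA spiked into the labelling reactions, were spotted 35 times each, with median intensities between 321 and 39202. Their log2 ratios ranged from −2.79 ± 0.02 to 3.02 ± 0.03 (mean ± SD, 35 spots), and 7 of the 10 were beyond 2-fold. The 13 bright corner spots had a log2 ratio of 0.01 ± 0.02. These controls do not cover the dim levels where most 2-fold differences lay. Among other control probes, DCP_22_7 (median intensities 82.9 with DMSO and 637 with RK-552) had a log2 ratio of 2.95 ± 0.23. The dimmer DCP_22_9 (7.28 and 11.2) had 0.67 ± 0.74 (mean ± SD, 2 spots each).

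The spread between repeat spots showed which differences the array could resolve. For the 6 repeat-spotted probes above the floor with a level under 16, the median SD between spots of one probe was 0.67, against an SD of 0.58 across all probes of that level. For the 7 with a level of 16 to 64 these SDs were 0.32 and 0.39. At these dim levels the SDs are not fully alike. Repeat-spotted probes passed the floor on the mean of their spots, so single spots below it could enter their SD. A probe spotted once had its only spot above both floors. With these SDs a 2-fold difference of a probe spotted once was not separable from spot noise at a level under 16, where 421 of the 531 differences lay. From a level of 64 to 256 the SD between spots was 0.10 and that across probes 0.23. At 256 to 1024 they were 0.06 and 0.16, at 1024 to 4096 they were 0.03 and 0.13, and at 4096 or more they were 0.02 and 0.13.

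**Figure D2:**
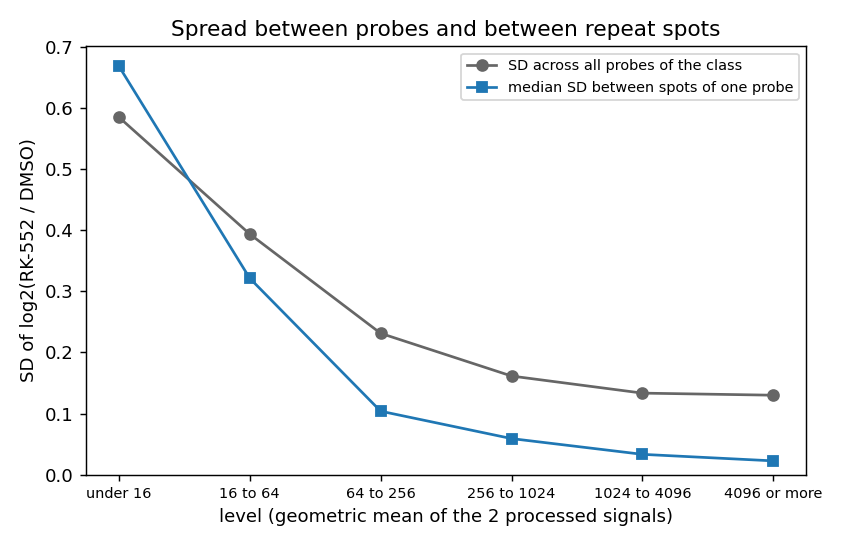
The x axis gives classes of level (geometric mean of both intensities) and the y axis the SD of log2(RK-552 / DMSO): grey circles are the SD across all probes above the floor in the class, blue squares the median SD between the 10 spots of a repeat-spotted probe. The SD between spots falls from 0.67 to 0.02, and the SD across probes from 0.58 to 0.13. Repeat-spotted probes passed the floor on the mean of their spots, so at dim levels single spots below it could enter their SD.

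Small differences of bright probes exceeded the noise between spots. Of 240 repeat-spotted probes with a level of 256 or more, 0 differed by 2-fold. In 145 of them (60.4%) all 10 spots lay on the same side of 0, in 61 higher and in 84 lower with RK-552, whereas spot noise around 0 would place 0.20% there. The split of 61 and 84 became 231 and 0 after centring on the median of all probes, 67 and 71 with an equal 75th percentile, 58 and 85 with quantile normalization and 62 and 80 with loess, so it gives no direction. The largest increase was from 298 to 421, a log2 difference of 0.50 ± 0.06 (SD, 10 spots), and the largest decrease from 865 to 685, a log2 difference of −0.34 ± 0.07 (SD, 10 spots). These differences hold between the Cy5 and Cy3 channels, and no exchanged-dye array was available to assign them to the treatment.

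The largest measured ratios of single probes were decreases. The probe A_24_P20369 had an intensity of 776 with DMSO and 27.4 with RK-552, 28.3-fold lower (log2 difference −4.82), and A_21_P0011402 had 509 and 26.8, 19.0-fold lower (−4.25). The probes that rose most were dimmer. A_33_P3241393 had an intensity of 5.70 with DMSO, which lies within the range of the negative-control spots (up to 8.97 in that column), and 31.3 with RK-552. Against the highest of those spots its RK-552 intensity was 3.49-fold higher, and its measured log2 difference was 2.46. The ratio of 3.49 is not a lower bound, because it leaves out noise in the probe's own spot. The level of A_33_P3241393 lay under 16, where a 2-fold difference of a probe spotted once was not separable from spot noise. A_21_P0012617 had 25.7 and 117, 4.55-fold higher (2.19). Each of these probes was measured by 1 spot, and with 50 added to both intensities A_33_P3241393 dropped below 2-fold (0.55). Among the 12 largest decreases, log2 differences ran from −4.82 to −2.28. Among the 12 largest measured increases, 10 had a DMSO intensity within the range of the negative controls, so their exact folds and their order carry no meaning. The same holds for 249 of the 355 probes counted as 2-fold higher. No such count can be made for the decreases, because the RK-552 floor of 5.17 already lay above the highest negative control of that column (3.86), while the DMSO floor of 5.12 lay below its own. All 24 were spotted once, and 4 of the decreases and 0 of the increases had a level of 64 or more.

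A further 2170 probes lay above the floor only with RK-552 and as many only with DMSO, numbers that are equal because each column's floor was its own median. Set against the floor of the other sample, 346 of the probes above it only with RK-552 were at least 2-fold higher, and 184 of those above it only with DMSO were at least 2-fold lower. The largest ratio to that floor was 5.03-fold higher with RK-552 and 8.06-fold lower, and 4 and 6 probes respectively had a ratio of 4-fold or more. The DMSO floor of 5.12 lay within the range of the negative controls, so ratios to it are not lower bounds. All of these probes had a level under 16, where a 2-fold difference of a probe spotted once was not separable from spot noise. Against the highest negative-control spot of the DMSO column, 14 of the probes above the floor only with RK-552 stayed at least 2-fold higher, the largest 2.87-fold.

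The probes fell into 7 series by the first part of their ID, whose meaning the deposited data do not state. In the A_23 series, 69.0% of probes lay above the floor with a median level of 411, and 47 were 2-fold higher and 27 lower, 0.91% of 8158. The A_24 and A_32 series were similar in level, with medians of 236 and 248, and 0.88% and 0.96% of their probes differed by 2-fold. The A_21 and A_22 series were dim, with 24.8% and 26.4% of probes above the floor and median levels of 30.8 and 26.4. In these, 3.51% of 2932 and 3.98% of 3242 probes differed by 2-fold. The A_33 series lay between, with a median level of 99.6, 120 probes higher and 57 lower, and the A_19 series had 7 higher and 2 lower of 435.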

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

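The comparisons with stray spots, with repeat-spot noise, with quantile normalization and with the place of the floor were chosen after the results were seen, and those with ERCC spots and with loess were written down before their values were computed. Of the 96 ERCC control probes, which match synthetic spike-in RNA rather than human transcripts, 1 was brighter than all 308 negative-control spots in both columns. This probe, ERCC-00148_99, had median intensities of 49.5 with DMSO and 65.5 with RK-552 over 9 spots, with a log2 difference of 0.23 ± 0.22 (SD between spots), and was noted because it is a signal outside the main measurement.

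Among probes with a level of 64 or more that were spotted once, 5 of 15871 differed by 2-fold, among them the largest decreases. Of 2580 repeat spots of this level, 1 strayed by 1 or more on the log2 scale from the median of its probe, at −2.04 against −0.15, and it widened that probe's SD to 0.61 from 0.08 without it. That rate gives 6.15 such probes (95% Poisson interval 0.16 to 34.3), which includes the 5. Because the rate rests on 1 stray spot, the interval is too wide to decide for or against isolated bad spots. The 4 decreases among the 5 had log2 differences from −4.82 to −4.10, and no repeat spot strayed as far. A response to RK-552 stays open, since neither probe annotation nor a second culture bears on the 5. Of the 258 repeat-spotted probes of this level 0 were 2-fold changed. At the rate of 5 in 15871 they are too few to expect any, so this count does not decide.

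Among dim probes above the main floor, 2-fold higher values outnumbered lower ones, 354 to 172. The excess does not hold under every floor: above the highest negative-control spot of each column, counts over all levels were 106 higher and 296 lower, a floor that by its construction drops higher and admits lower values, and 249 of the 355 higher probes had DMSO intensities within the negative-control range. After loess, 62.4% of the 2-fold differences under a level of 64, counted anew, were higher (95% interval 58.3% to 66.3%). By loess alone, a dye bias that depends on level is argued against as the whole cause. Over all levels, 258 of the 367 higher and 167 of the 225 lower probes after loess were also counted before it. Quantile normalization gave 51.5% (47.0% to 56.0%). It sets both columns to the same distribution, which can itself draw the balance towards 50%, a point that was not tested. Loess and quantile normalization thus differ, and a bias that depends on level is not settled for this excess. Where the floor lies in each column cannot have set the excess at a level of 16 to 64, since all 6261 probes of that level were above both floors and 66 were higher and 39 lower (62.9% higher, 95% interval 52.9% to 72.1%). Under a level of 16, where 68.4% were higher, it stays open, because most probes there lie at or below a floor. Noise near the floor was tested on ERCC spots above the floor under a level of 64, of which 0 of 27 were 2-fold higher. That share of 0% has an upper bound of 12.8%, which includes the 3.28% of the array's probes. The 27 spots came from 12 ERCC probes, so they are not independent. Their median level was 7.95, against 19.2 for the array's dim probes. The spots are too few to decide. No biological explanation could be tested.

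Bright probes spread further apart than their spots did. Over 240 repeat-spotted probes with a level of 256 or more, the SD between probe means was 0.126, against 0.019 (upper bound 0.021) from spot noise, and it was 0.126 after loess and 0.124 after quantile normalization, which argues against spot noise and against a bias that depends on level as the whole cause. In the upper tail, 16 probes spotted once were 1.5-fold higher (log2 0.59 to 0.82), where up to 15.7 could come from upward stray spots (0 of 2400 repeat spots), so bad spots are not settled for these. A dye bias of single probes may give the same spread as a response to RK-552, and with 0 arrays with exchanged dyes they cannot be told apart.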

How the results depend on the processing

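The counts of 2-fold higher and lower probes (355 and 176) stayed within 1.5 times under an equal 75th percentile (366 and 170), quantile normalization (256 and 244) and loess (367 and 225). They moved with centring on the median of all probes (1046 and 55), with 50 added to both intensities (1 and 9), with the floor at the 70th percentile (1 and 1), above the floor in at least 1 sample (1052 and 1788) and with no floor (1052 and 23200), the last 2 because values at the array's lower limit enter. Thresholds of 1.5-fold and 3-fold gave 1423 and 817, and 32 and 21. With floors chosen after seeing the data, the counts were 106 and 296 above the highest negative-control spot and 1 and 4 at a level of 64 or more. The named probes kept their direction under the 5 settings that rescale or offset the intensities, with log2 differences from −4.85 to −3.42 for A_24_P20369, −4.29 to −2.86 for A_21_P0011402, 1.14 to 2.498 for A_21_P0012617 and 0.55 to 2.77 for A_33_P3241393, whose DMSO intensity lies within the negative-control range so that these are not exact folds. The median SD between repeat spots was 0.038 and stayed between 0.037 and 0.040 with loess or another floor. No replicate could be left out with 1 sample per group. Log2 differences were taken within each spot, but no pairing across replicate cultures was possible because each group held 1 sample. Gene list medians, the target transcript and the brightest probe per gene were not run, for lack of probe annotation. Signal over background limits the comparison below a level of 64. There 592 simulated unchanged probes passed 2-fold and 526 differences were observed, with the simulated noise taken from 13 repeat-spotted probes. No floor was applied to the simulated values, whereas the observed probes lay above it in both samples. The counts therefore cannot show whether spot noise covers the observed differences.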

Other observations

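Among bright probes that differed by 1.5-fold or more, increases outnumbered decreases. At a level of 256 or more, 16 probes were at least 1.5-fold higher with RK-552 and 1 was at least 1.5-fold lower. These counts were 17 and 1 with an equal 75th percentile, 16 and 1 with loess, 14 and 1 with quantile normalization, 10 and 1 with 50 added to both intensities, and 424 and 1 with centring on the median of all probes. The increases were found at all brighter levels, with 7 probes at 256 to 1024, 5 at 1024 to 4096 and 4 at 4096 or more, and their median log2 difference was 0.65. Each of the 16 was spotted once, and up to 15.7 such probes could come from upward stray spots. Without an exchanged-dye array, higher with RK-552 cannot be told apart from higher in Cy5. Among the repeat-spotted probes of this level, all spots were higher in 61 and lower in 84, a split that moved with the scaling. Of the 240 repeat-spotted probes of this level, 0 changed by 1.5-fold in their mean, too small a number to show whether such a tail repeats across spots.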
